A study of Mus musculus with 5 samples.

How the data were processed

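The series holds 5 RIP-PEN-seq libraries from mouse Hepa1-6 cells, a hepatoma line, that stably overexpress FLAG-15.5K, a tagged form of the protein Snu13. RIP-PEN-seq is RNA immunoprecipitation followed by small RNA library preparation and sequencing. Per the labels' protocols, complexes were recovered from lysate with an anti-FLAG antibody on protein G beads, ribosomal RNA was removed from the recovered RNA, and libraries were made with a TruSeq small RNA kit. All 5 libraries form 1 group, with replicate numbers 1 to 5 taken from the titles. An input, an unspecific antibody or a parental cell line was not analysed here, so no value is an enrichment and no comparison between groups was made. The labels do not say that the libraries came from separate cultures, so the spread between them may be technical.

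Per the submitters' processing notes, cutadapt 2.8, STAR and bedtools were used with build mm10. The role of each tool, its settings, and how an RNA was called and counted are not given in the sources used here. The deposited table has 43 RNAs and 18 columns: name, coordinates, sequence, length, distances, a score, 5 library values, their sum and a gene label. The deposited library values are in RPM, read numbers scaled to a common library size, per the file headers, where the heading of the summed column names the unit. That column equals the sum of the 5 library columns, and which reads make up that library size is not given in the sources used here. The deposited score has no stated definition, and the report gives what it was found to equal. The distance columns were matched to the sequences in the same way. Coordinates are given 1-based on mm10, while the deposited starts count from 0.

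The table was read with Python 3.11.15 and pandas 2.3.3. Tests used scipy 1.17.1, numpy 2.4.6 and numba 0.67.0, and figures matplotlib 3.10.9. Gene models came from GENCODE M21 on the same assembly, and each of the 31 versioned transcript IDs in the table is in that release. No genome sequence was used here. For correlations between libraries, library values were put on the scale log2(RPM + 1). For associations across RNAs and the class difference, the mean RPM over libraries was put on that scale. No filter on low values was used. Associations across RNAs used two-sided permutation tests with 100000 resamples. RNAs are not independent replicates, so those p-values describe the list. The class difference was tested over all splits of the RNAs, an exact test in place of the 100000 resamples set beforehand. Motif counts were set against 1000 dinucleotide-preserving shuffles of each sequence. Intervals of shares are exact Clopper-Pearson intervals at 95% and cover counting error only.

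Read depth was read from the low values. In each library, the RPM step was sought of which the values are whole multiples within 0.05 steps. The rule first used took the largest step that made a share of 0.7 of the values whole. After its result was seen, it was replaced by the largest step for which no finer step made over 0.2 more of the values whole. The change affects library 2 alone, whose implied depth is 36300000 reads under the later rule and 72600000 under the first. Because only 80% of the values above 0 came out whole, no count model of abundance was fitted. Step counts rounded to whole numbers served to look for a library deposited more than once and to tally the lowest values. The implied depths also gave the expected reads, the expected molecules and the Poisson draws used for the values at 0. Those quantities rest on reading 1 step as 1 read. In data simulated for 43 RNAs, the step gave the depth within 1% in 97 of 100 libraries. By construction, the simulated libraries held no value of 1 read. They also held a smaller share of fractional values than library 2, where 9 of 28 values above 0 were not whole. The simulation therefore does not settle the depth of library 2, on which the rules differ. In other simulated data for 43 RNAs, the class test called 0 of 20 data sets without an effect and 20 of 20 with a shift of 4 log2 units. The rank correlation called 0 of 20 without and 20 of 20 with an effect of length, simulated with a noise SD of 0.5 log2 units. The shift of 4 is large beside the real medians of log2(mean RPM + 1), 0.242 in intronic and 0.271 in other RNAs. Neither simulation checked the power for smaller effects.

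The RNAs named were fixed by a rule before the data were examined: the 10 with the highest mean RPM, the longest and the shortest, those hosted by a gene in 7 fixed lists, those bearing the name of a known snoRNA, and hosts of several RNAs. The rule named 12 RNAs. No RNA bears such a name and no host gene has more than 1 RNA. Other RNAs are named where a count is small or a position or value is unusual, and were chosen after their values were seen. The relation of abundance to the score was also added after the data were seen. Alternatives included another pseudocount, other motif definitions, other intron definitions, and leaving out each library in turn.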

Results

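The libraries address which noncoding RNAs associate with the tagged protein FLAG-15.5K in Hepa1-6 cells. The protein, also called Snu13, binds kink turns, bent RNA helices formed in box C/D snoRNAs and in U4 snRNA. The table lists 43 RNAs called bktRNAs, a name used for backward kink-turn RNAs, in which box D lies upstream of box C. The listed RNAs add up to 70.4, 80.1, 97.2, 95.5 and 62.2 RPM in libraries 1 to 5, a small part of each library. If 1 step in the low values is 1 read, the libraries hold 34200000, 36300000, 31700000, 30700000 and 17400000 reads, so library 5 is the shallowest. Of the 215 values, 85 are listed at 0. Libraries 1 to 5 list 30, 28, 31, 25 and 16 RNAs above 0.

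Abundance among the listed RNAs was led by bktRNA1, from an intron of Cwf19l1, with 55.7 RPM ± 12.6 (SD, n = 5). It took 68.3% ± 3.63 (SD, n = 5) of the listed RPM per library, from 65.0% in library 5 to 74.2% in library 4. Of its 244 nt, 144 overlap the annotated snoRNA Gm24336. Whether reads of that snoRNA are counted in these values is not given in the sources used here. The next RNA, bktRNA2, lies in Khdrbs1, which encodes an RNA-binding protein, and had a mean of 5.93 RPM ± 3.70 (SD, n = 5). bktRNA3, in Impa2, an inositol monophosphatase gene, had 4.82 RPM ± 6.45 (SD, n = 5), and rests on library 5: without it the mean was 1.93 RPM, and bktRNA3 ranked 5 rather than 3 by mean RPM. The lowest bktRNA1 value, 40.4 RPM, lies above the highest value of any other listed RNA, 16.4 RPM for bktRNA3.

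The remaining 7 of the 10 most abundant RNAs ranged from 0.678 to 2.06 RPM. bktRNA4, in the myosin gene Myo5b, had 2.06 RPM ± 1.25 (SD, n = 5), and bktRNA5, in Trrap, a gene for a component of histone acetyltransferase complexes, had 1.64 ± 0.975. bktRNA6 in Smco4 had 1.31 RPM ± 0.955, bktRNA7 in Hnrnpul1 had 1.20 ± 0.729, and bktRNA8 in Ppl, the periplakin gene, had 1.09 ± 0.627. bktRNA9 in the collagen gene Col8a1 had 0.710 RPM ± 0.454, and bktRNA10 in Rab3gap1 had 0.678 ± 0.627. The 10 RNAs hold 92.6% of the summed RPM, and the other 33 each had a mean of 0.543 RPM or less.

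Several of these means include a value listed at 0. In library 5, bktRNA2, bktRNA4, bktRNA5, bktRNA7 and bktRNA8 are listed at 0, while bktRNA2 had 5.29, 7.47, 9.86 and 7.04 RPM in libraries 1 to 4. bktRNA6 and bktRNA10 are at 0 in library 3 and bktRNA9 is at 0 in library 4. Of the 10 most abundant, bktRNA3 went the other way, with 1.81, 1.79, 2.28 and 1.85 RPM in libraries 1 to 4 and 16.4 RPM in library 5. Beyond the 10, bktRNA19 in Pola1 had 1.32 RPM in library 5 and at most 0.331 RPM in the others. bktRNA27 in Aagab had 0.576 RPM there and at most 0.110 RPM in the others. In all, library 5 lists 27 of the 43 RNAs at 0. The RNAs above 0 in each of the 5 libraries were bktRNA1, bktRNA3, bktRNA12 in D3Ertd751e, bktRNA15 in Swap70 and bktRNA16 in Alpk1. This count of 5 rests on library 5, without which 12 RNAs are above 0 in each library. Another 20 RNAs are above 0 in exactly 2 libraries, and none in fewer. Whether 2 libraries were required for listing is not given. Such a rule would bear on the correlations between libraries and on the expected reads given below.

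**Figure D1:**
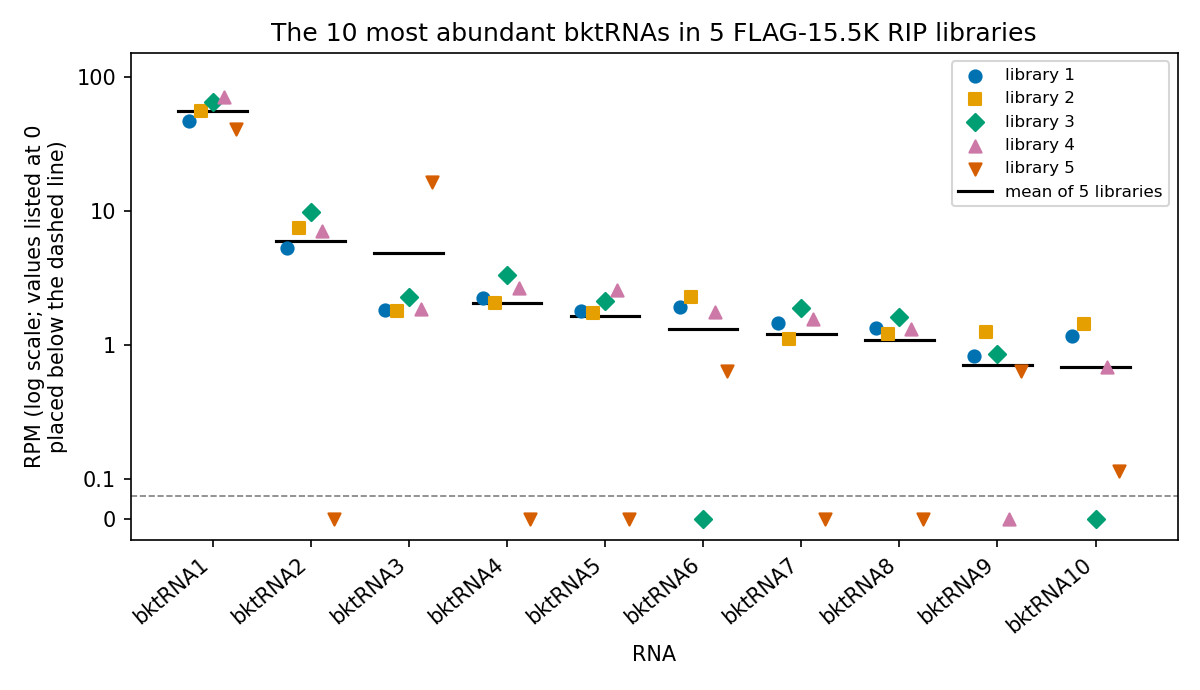
RPM of the 10 most abundant bktRNAs in each of the 5 FLAG-15.5K RIP libraries, on a log scale, with values listed at 0 placed below the dashed line and the mean of the 5 libraries as a bar. bktRNA1 lies between 40.4 and 70.9 RPM in each library, and library 5 has bktRNA3 at 16.4 RPM and 5 of the other RNAs at 0.

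Across the 43 RNAs, pairs among libraries 1 to 4 had Pearson correlations of log2(RPM + 1) between 0.898 and 0.975, and pairs with library 5 between 0.640 and 0.697. These values are across RNAs, and bktRNA1 carries much of them. Without bktRNA1 the ranges were 0.748 to 0.933 and 0.145 to 0.256. Spearman correlations ranged from 0.384 to 0.721 among libraries 1 to 4 and from -0.0703 to 0.270 with library 5. In step counts rounded to whole numbers, the most similar pair, libraries 1 and 4, differed by more than counting noise (chi-square 179, 35 degrees of freedom, p = 2.97e-21), so no library was counted as a repeat of another. This check covers counting error only and treats reads as independent molecules.

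bktRNA1 lies on chromosome 19 at 44113879 to 44114122 of mm10, on the minus strand, in intron 11 of Cwf19l1. The intron runs from 44113794 to 44114523 and is 730 nt long. The RNA is 244 nt, starts 401 nt after the 5′ splice site and ends 85 nt before the 3′ splice site. Its 5′ part covers 144 nt of the annotated snoRNA Gm24336 (44113979 to 44114124), which starts 2 nt further upstream. The RNA runs 100 nt past the annotated 3′ end of Gm24336, and its box D and box C both lie in that added part.

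**Figure D2:**
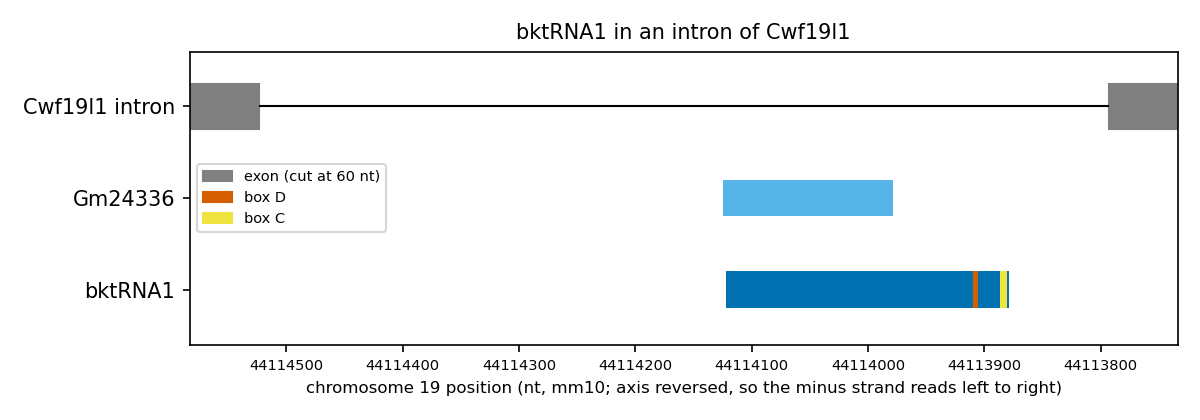
Map to scale of intron 11 of Cwf19l1 on chromosome 19 (position in nt, mm10, axis reversed so that the minus strand reads left to right), with exon ends in grey, the annotated snoRNA Gm24336 and bktRNA1. Box D and box C of bktRNA1 lie in the 100 nt past the annotated end of Gm24336.

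On position in genes, the table calls 36 of the 43 RNAs intronic (83.7%, 95% Clopper-Pearson interval 69.3% to 93.2%), 5 intergenic (11.6%) and 2 exonic (4.65%). The exonic RNAs are bktRNA14 in the 3′ UTR of Eme1 and bktRNA18 in that of Gpd1l. The intergenic RNAs include bktRNA13, a 28 nt RNA on chromosome 7 (81774511 to 81774538, plus strand), which had 0.554 RPM in library 2 and 1.54 RPM in library 3 and is listed at 0 in the others. bktRNA2 lies on chromosome 4 (129717611 to 129717646, minus strand) in intron 8 of Khdrbs1, and bktRNA3 on chromosome 18 (67294589 to 67294656, plus strand) in intron 1 of Impa2. bktRNA4 (chromosome 18, 74452546 to 74452578) and bktRNA6 (chromosome 9, 15501505 to 15501532), both on the plus strand, also lie in intron 1 of an annotated transcript of their hosts.

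All 38 RNAs over a GENCODE gene, bktRNA1 to bktRNA10 included, lie on the same strand as the gene, and 2 of them, bktRNA14 and bktRNA26, also lie opposite a gene on the other strand. The share differs from one of 50% (exact two-sided binomial test, p = 7.28e-12, lower bound of the share 90.7%). Whether strand was used in calling or listing the RNAs is not given in the sources used here. Such a rule would fix this result in advance. The 38 host genes are distinct, 37 protein-coding and 1 of the provisional class TEC, Gm48138, which is the label the table gives bktRNA20. In the annotation bktRNA20 lies in an intron of Col4a3bp and over an exon of Gm48138. Of the 36 intronic RNAs, 5 also lie over an exon of some transcript on the same strand: bktRNA1 (Gm24336), bktRNA9 (Col8a1), bktRNA17 (B230118H07Rik), bktRNA20 (Gm48138) and bktRNA35 (Plb1). Host introns were long, with a median of 13277.5 nt, and bktRNA4 lies in one of 70370 nt.

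The RNAs were short. Their median length was 38 nt (quartiles 32 and 54.5 nt), and 29 of the 43 were under 50 nt. bktRNA1 was the longest at 244 nt, followed by bktRNA29 in Paxbp1 at 151 nt and bktRNA25 in Dpysl2 at 100 nt. The shortest, at 28 nt, were bktRNA6 in Smco4, bktRNA13, and bktRNA38 in Gpcpd1, which is above 0 in libraries 1 (0.0584 RPM) and 2 (0.165 RPM). Of the 10 most abundant RNAs, bktRNA2 had 36 nt, bktRNA3 had 68 nt, bktRNA5 had 56 nt and bktRNA8 had 47 nt.

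On the order of the boxes, each of the 43 RNAs has box D (CTGA) before box C, counted with up to 1 mismatch to RTGATGA. Shuffled sequences gave a median of 5 such RNAs and at most 12 (permutation p = 0.000999, the smallest that 1000 shuffles give). The forward order, box C before box D, occurred in 1 RNA (2.33%), against a median of 5 in shuffles (permutation p = 0.998). With an exact box C, 27 RNAs (62.8%) had the backward order and 0 the forward order. Each listed RNA has CTGA at its deposited upstream distance and RTGATG at its downstream distance, so the list appears to be selected on these boxes. The shuffle test therefore describes the selection and is not independent evidence for it.

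In 35 RNAs box D starts after 4 nt, and in 31 box C is followed by 2 nt, as in bktRNA2 (36 nt). bktRNA1 stands apart with 213 nt before box D, where the others have 2 to 6. In 41 of the 43 RNAs the deposited score equals the summed hydrogen bonds of the uninterrupted Watson-Crick stem between the boxes, at 2 per A-U and 3 per G-C pair. The exceptions were bktRNA14 (score 11, bonds 8) and bktRNA29 (score 14, bonds 6). In those 41 the stem had 3 to 8 base pairs (median 4) and the loop 1 to 73 nt (median 11). These are complementary bases read from the sequence, with a loop of 1 nt allowed, and no folding was computed. bktRNA8 in Ppl had the longest stem, 8 base pairs with a score of 21, and bktRNA1 had 6 base pairs with a score of 17.

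**Figure D3:**
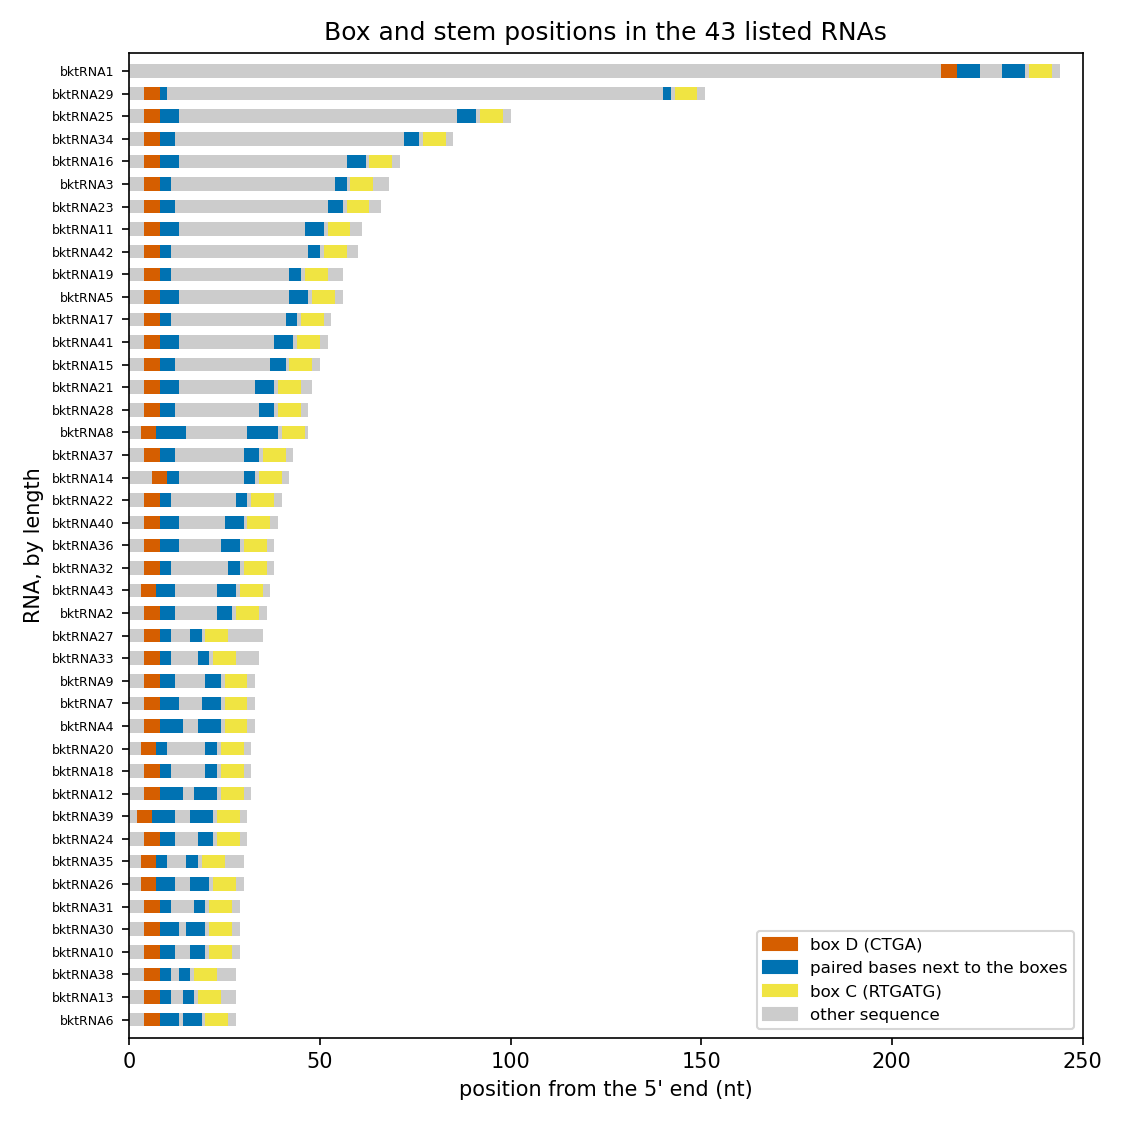
Position of box D, of the paired bases next to the boxes (complementary in sequence) and of box C in each of the 43 RNAs, in nt from the 5′ end and to scale, sorted by length. Box D lies 2 to 6 nt from the 5′ end in each RNA except bktRNA1, where 213 nt precede it.

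Abundance was compared with length, score and position across the 43 RNAs, in a family of 5 relations with Benjamini-Hochberg adjustment. Between log2(mean RPM + 1) and log2 length, Spearman's rho was 0.0682 (permutation p = 0.663, adjusted p = 0.829) and Pearson's r was 0.450 (permutation p = 0.0149, adjusted p = 0.0743). The Pearson value rests on bktRNA1, without which it was -0.0113. Without bktRNA1 and bktRNA29, the RNAs farthest from the median length, it was 0.0457. With the score, Spearman's rho was 0.204 (permutation p = 0.191, adjusted p = 0.318) and Pearson's r was 0.336 (permutation p = 0.0303, adjusted p = 0.0757). That Pearson value was 0.170 without bktRNA1 (permutation p = 0.274), and 0.112 without bktRNA1 and bktRNA8, the RNAs farthest from the median score.

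The 36 intronic RNAs had a median of 0.183 RPM and the other 7, such as bktRNA13, bktRNA14 and bktRNA18, a median of 0.207 RPM. The difference in median log2(mean RPM + 1), intronic minus other, was -0.029 (exact two-sided permutation test over 32224114 splits, p = 0.946, adjusted p = 0.946). With means in place of medians the difference was 0.41 (exact p = 0.315), the opposite sign. No relation passed the adjusted threshold of 0.05.

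Of the 7 gene lists fixed beforehand, 1 held a host gene. Hnrnpul1, an hnRNP gene that hosts bktRNA7, is 1 of 68 splicing and hnRNP genes with an intron in the annotation (Fisher's exact test against 33329 genes, p = 0.0747, adjusted p = 0.523). bktRNA7 lies at 25730407 to 25730439 on chromosome 7, minus strand, and the table labels it with the repeat PB1D9 of the Alu family. The lists of ribosomal proteins, translation factors, snoRNA host noncoding genes, box C/D snoRNP and nucleolar proteins, hepatocyte genes and chaperones held 0 hosts. Each of these 6 had a p of 1. The 6 lists hold 8 to 193 genes with an intron out of 33329, so 0 among 38 hosts does not show that such genes are avoided.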

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

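The tests of library 5 and of the values at 0 were chosen after those results were seen, and the test of shared sequence copies before its result was seen. In 17 sets of 5 library values, 3 had a library far from the others, and it was library 5 each time. Chance gives about 1 in 20 independent sets, but these sets overlap, so the count is not a test. bktRNA3, in Impa2, had 16.4 RPM in library 5 against 1.79 to 2.28 RPM in the other libraries. bktRNA8, in Ppl, is listed at 0 RPM in library 5 against 1.20 to 1.61 RPM in the others. The mean length weighted by RPM, without bktRNA1, was 64.1 nt in library 5 against 43.7 nt or less in the others. This mean shares bktRNA3 with the value above, and without bktRNA3 as well, a setting chosen after the data were seen, it was 52.4 nt against 37.8 to 41.7 nt. Over all 43 RNAs, 7 had such a library.

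Library 5 lists 16 RNAs above 0 and correlates least with the other libraries. Its implied depth of 17400000 reads is the lowest, but 5 RNAs listed at 0 there (bktRNA2, bktRNA4, bktRNA5, bktRNA7 and bktRNA8) have 20 or more expected reads from their mean in the other libraries, and bktRNA2 has 129, a count that covers counting error only. Reads can be copies of fewer molecules. The spread between libraries 1 to 4, pooled over these 5 RNAs, gives at least 6.04 expected molecules in library 5 (estimate 12.5, chance of a 0 at the bound 0.00238). RNA by RNA the lower bounds were 0.947 for bktRNA2, 1.33 for bktRNA4, 1.73 for bktRNA5, 1.32 for bktRNA7 and 3.61 for bktRNA8. Only the last reaches 3, where the chance of a 0 falls under 0.05. The pooled bound argues against depth as the whole cause for these 5 RNAs as a set. It takes library 5 to hold as many molecules per read as the other libraries, and the 5 RNAs were picked for their 0 there. A selection of longer RNAs in library 5 may be a candidate explanation. The AUC of length was taken among the 11 RNAs with 10 or more expected reads, for the 5 above 0 against the 6 at 0. It was 0.433, with ties counted at 50% (exact one-sided permutation p = 0.669). The test cannot decide this, because 11 RNAs are few and it ignores how high a value is. It also leaves out long RNAs with fewer expected reads, such as bktRNA29 and bktRNA25. The weighted mean length given above was longer in library 5, so this stays open. No biological explanation was tested, since the libraries form 1 group, and a difference in culture, precipitation or library preparation remains possible.

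Values at 0 also occur in libraries 1 to 4, and over all libraries 18 of the 85 values at 0 have 10 or more expected reads, which argues against chance loss of independent reads and covers counting error only. Chance loss of few molecules copied by PCR stays open for bktRNA6 and bktRNA10 in library 3 and bktRNA9 in library 4, with 20 or more expected reads. Pooled over the 3 values, the spread between the other libraries gives at least 1.61 expected molecules (estimate 4.34). Without library 5 the pooled bound is 3.94 (estimate 14.5), which would argue against such loss, so the pooled answer depends on that library. RNA by RNA, the bounds without library 5 were 2.82 for bktRNA6, 0.407 for bktRNA10 and 0.817 for bktRNA9, each under 3. For the other 9 values the pooled bound is 0.487 (estimate 0.814, or 1.18 without library 5). The estimates by RNA ran from 0.533 for bktRNA13 in library 4 to 2.50 for bktRNA17 in library 2. Without library 5 they ran from 0.703 for bktRNA19 in library 4 to 20.7 for bktRNA17 in library 2, so they too depend on that library. Spread from any other source lowers these estimates as well, so this part also stays open. A minimum of 2 reads per listed value is consistent with the absence of values of 1 step, where 15 values have 2 steps and 8 have 3, and where Poisson draws, which take reads as independent, would give 26.3. No biological explanation was tested.

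Of the 130 values above 0, 26 were not whole multiples of the step, in 14 RNAs, among them bktRNA1 in each of the 5 libraries. Reads shared with other copies of a sequence may give such values. RNAs with such values shared sequences of 20 nt with fewer other genes than the remaining RNAs, by -0.35 in mean log2(genes + 1). The permutation p was 0.624, and only 5 RNAs had any such gene counted. bktRNA5, in Trrap, shares one with 917 genes and has whole values alone, while bktRNA1 has a count of 0. That count leaves out Gm24336, the annotated snoRNA that 144 nt of bktRNA1 overlap, so reads shared with it are not covered. The search covered GENCODE transcripts and not introns or intergenic copies, so it does not decide the matter, and no biological explanation was tested.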

How the results depend on the processing

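Settings chosen after the data were seen are those without replicate 5 for the associations, the count of RNAs in every library with each of its left-out replicates, without bktRNA1, the median over libraries, the strict intron definition, the relation to the score and the first step rule. A cut at the median of the mean RPM leaves 22 of the 43 RNAs, by its construction. The number of RNAs above 0 in every library ranged from 5 to 12 when each replicate was left out, with 12 without replicate 5. The median Pearson correlation between libraries was 0.899 with a pseudocount of 1 and 0.685 with 0.1; the cause was not tested. The rank correlation of abundance with length, 0.0682, turned to -0.0199 without the 4 most abundant RNAs, to -8.11e-05 without bktRNA1 and to -0.0119 without replicate 5. It was 0.250 with the median over libraries (permutation p = 0.107), and none of these passed the test. The class difference of -0.029 turned to 0.41 with means, which weigh the abundant intronic RNAs more than medians do. A difference in means without those RNAs was not computed. Pearson's r with length went from 0.450 to -0.0794 without the 4 most abundant RNAs (permutation p = 0.634). That with the score went from 0.336 to 0.170 without bktRNA1 (permutation p = 0.274). Apart from these Pearson values, the other settings kept their direction and side of the threshold. The bktRNA1 mean was 51.9 to 59.5 RPM and its share 66.8% to 69.1% when each replicate was left out. The intronic share was 72.1% with no exon overlap. The backward box order held in 62.8% to 100% of RNAs and passed the shuffle test under each definition. Since the list appears to be selected on these boxes, that outcome describes the selection. Under the first step rule, 22 values at 0 had 10 or more expected reads, against 18, and 24.1 values of 1 read were expected, against 26.3. Depth limits the weakest RNAs: the step is 0.0276 to 0.0576 RPM, so if a step is 1 read bktRNA43, with a mean of 0.0299 RPM, rests on a few reads. No paired analysis was possible because the libraries form 1 group.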

Other observations

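The test of intron position was chosen after the position of bktRNA1 had been seen. Among the 43 RNAs, 7 carry a repeat label in the table, all in introns: 3 SINE, 2 LTR, 1 LINE and 1 simple repeat. Their means ranged from 0.0447 RPM for bktRNA38 (an MTD element in Gpcpd1) to 1.20 RPM for bktRNA7 (PB1D9 in Hnrnpul1). bktRNA11, in Mob3b, lies in a B3A element of the B2 family with 0.543 RPM ± 0.307 (SD, n = 5), and bktRNA23, in Xpo5, in a TGG repeat with 0.174 RPM ± 0.175 (SD, n = 5). bktRNA15, in Swap70, had the most even values among the RNAs above 0 in each library, from 0.305 to 0.461 RPM. Besides bktRNA14, which lies opposite Lrrc59, bktRNA26, in Tbc1d22a, lies over a gene on the other strand, A930001M01Rik.

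Placement near the 3′ splice site, where intronic box C/D snoRNAs often lie, was tested as a hypothesis for the intronic RNAs. bktRNA1 ends 85 nt and bktRNA34, in Tead3, 92 nt before it, so 2 of 36 lie within 100 nt, where uniform placement in the same introns gives 1.03 (exact one-sided p = 0.275). With so few RNAs the test leaves open whether placement near the splice site is favoured. The median distance was 5770 nt to the 3′ splice site and 2356.5 nt to the 5′ splice site, and 0 RNAs lie within 100 nt of the latter.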
